A study of Drosophila melanogaster with 4 samples.

How the data were processed

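RNA came from 20000 to 40000 sorted neuroblasts per sample and was amplified to amino-allyl RNA, of which 1.5 ug was coupled to Cy3 and hybridised to 1 array per sample, per the labels' protocols. Background-subtracted intensity per spot was made with Agilent Feature Extraction 10.7.3.1 from 1 colour per array, with no normalization between arrays, per the file headers, which name the build dm3 for the array design. All 4 arrays lay on 1 slide with 1 scan, so slide and scan could not differ between groups. Replicate 1 of both groups lay in row 1 of the slide and replicate 2 in row 2.

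The authors' table of processed values holds a score per probe for 17822 probes. The method behind it is not given in the sources used here. Its 4 columns hold one set of values (median 0.00625 in each, from -4.28 to 5.50), as quantile normalization gives, in steps of 0.00125. Set against the scanner intensities of the same arrays, its differences between arrays ran in the same direction (r from 0.784 to 0.93 over the 6 pairs) with slopes from 0.706 to 1.74. The base of its log scale and the reference on which each probe was centred stay unknown, so that it served for counts of calls and for correlations only, never for folds.

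Samples were grouped by the genotype in their labels, and every array entered the fit. Intensities were divided by each array's 75th percentile over non-control probes, multiplied by the mean of these percentiles, set to a floor of 1 intensity unit and put on a log2 scale relative to that mean. Control spots were left out (1319 of 62976 spots). A probe was kept if it was well above background on both arrays of at least one group, and 30 probes with an outlier flag on any array were left out. No spot was saturated on any array (0 saturated). Each ID had a single spot. The 35366 kept probes were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. A probe not well above background on either array of a group has only a bound there. Its fold is then given as at least the ratio of the brighter group's mean to the mean, over the dim group's arrays, of the higher of the dimmest signal well above background and the probe's own signal.

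The rule fixed before the data were examined named eag, dpn and insc, the largest differences past the threshold, or, where fewer than 5 passed, the 10 probes per direction with the smallest p. Because the files do not pair IDs with genes, 2 probes per direction are printed. For the same reason the gene lists and cell type markers that had been fixed, and the distribution of calls over chromosomes, gave no value, and the brightest probe of a gene could not be chosen. Alternatives fixed before the data were examined changed the background correction (normexp with an offset of 50, on median spot and background signals since the files hold no mean signal), the normalization, the filter on dim probes, the variance model, the replicate number as a block, the source of values, the threshold and the arrays included. A raised floor of 34.7 intensity units after scaling, cyclic loess, a restriction to the probes of the authors' table and fits without the probes that were low on one array alone were added after seeing the data. When an array was left out, the set of kept probes was held fixed.

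The fit was tested on simulated data with the real probe means and with variances drawn from the prior that limma estimated (3.69 prior degrees of freedom), with noise independent between arrays. For eag mutant against eag wild type with 200 of 35366 probes changed, 0% of 2-fold, 4% of 4-fold, 80% of 8-fold and 70% of 16-fold changes were recovered at an adjusted p under 0.05. With 6000 probes changed, 24.2% of 2-fold and 81.13% of 4-fold changes were recovered, and 4.951% of unchanged probes had an unadjusted p under 0.05. The changes were 2-, 4-, 8- and 16-fold in equal numbers, 50 each among the 200 and 1500 each among the 6000. The many 8-fold and 16-fold changes among the 6000 ease the adjustment for smaller ones. Recovery of 2-fold and 4-fold changes would be lower where large changes are rarer. The simulated variances follow the model that limma assumes, while the real data hold probes that were low on a single array. Recovery in the real data may thus be lower, and an absence of calls there does not show that large changes are few. The number of arrays, 2 per group, limits the precision of every value.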

Results

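Gene expression was measured in neuroblasts, the neural stem cells of Drosophila melanogaster, on 4 one-colour oligonucleotide arrays. The cells carried a membrane GFP under insc-Gal4, a driver active in neuroblasts, and were sorted by FACS from dissociated brains. All 4 samples overexpressed dpn, which encodes Deadpan, a transcriptional repressor that maintains neuroblast identity. The groups differed in eag, the gene for the Ether-a-go-go voltage-gated potassium channel, with 2 eag mutant samples and 2 samples with wild type eag. The single comparison of the design addresses how the transcript profile of dpn-overexpressing neuroblasts differs when eag is mutated. The labels do not say whether the 2 samples of a group came from separate sorts, so the p-values measure the spread between these samples, which may be technical.

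Each array carried 61657 non-control probes, of which 59.15% and 53.37% were well above background on the arrays of eag mutant replicates 1 and 2, and 62.22% and 56.81% on those of eag wild type replicates 1 and 2. The 75th percentile of background-subtracted intensity was 417 and 278.2 in the eag mutant and 906.1 and 555.7 in the eag wild type, so that the mutant mean was 0.476 of the wild type mean before scaling. After scaling to this percentile, 35366 probes were tested. The files do not pair probe IDs with genes, and 0 of the IDs matched the gene table at hand. The level of eag itself could therefore not be read, and the results are given for probes. It might have helped to check the labels, although an allele can leave the transcript level unchanged.

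With all tested probes in the fit, no probe passed an adjusted p of 0.05 between eag mutant and eag wild type neuroblasts (limma with Benjamini-Hochberg adjustment, 0 higher and 0 lower, smallest adjusted p = 0.222, n = 2 per group). At an unadjusted p under 0.05, 6394 probes (18.08%) differed, against 1768 that would fall there by chance, and 3763 of them were higher and 2631 lower in the mutant. In 55.94% of probes both mutant arrays lay on the same side of both wild type arrays, where 33.3% is the share given by chance. These were 10072 probes above and 9713 below the wild type. Without the filter on background, which admits dim probes, the share on the same side was 44.59%. Among the probes at unadjusted p under 0.05, 2401 were at least 2-fold higher and 687 at least 2-fold lower in the mutant. The split into higher and lower depended on the processing. After quantile normalization 37.74% of such probes were higher in the mutant, after normexp background correction 71.73%, and with the 75th percentile 58.85%. Median centring gave 55.53% and cyclic loess 52.5%. With the 75th percentile and only the probes of the authors' table, the share was 48.59%. In the authors' table, limma also called 0 probes, with 3983 at an unadjusted p under 0.05, of which 45.42% were higher. Without the array of eag wild type replicate 1, 2729 probes passed an adjusted p of 0.05 in limma, 2298 higher and 431 lower, in a fit where the lone wild type array is assumed to vary like the mutant pair. Of these 2298, 1283 (55.8%) were probes that lay at least 4-fold below each other array on the array of eag wild type replicate 2, the only wild type array left in that fit. With all such probes left out, a choice made after seeing the data, 380 passed without eag wild type replicate 1, 46 of them lower. With all 4 arrays and these probes left out, 274 of 34075 passed, 238 higher and 36 lower, at adjusted p from 0.0384 to 0.0496 in limma. Since these probes were picked by their spread between the wild type arrays, leaving them out also changes the variance model that limma fits. The prior degrees of freedom went from 3.69 to 7.37, which draws the variances of single probes more strongly to the common trend. Replicate 1 against replicate 2, a contrast that holds no genotype effect, then gave 21 calls, with adjusted p in limma down to 7.82e-05. A difference between genotypes adds to the spread within its groups, so 21 may be too low as a baseline. Without eag wild type replicate 2 the count was 1, and without eag mutant replicate 1 or 2 it was 0, with 3254 and 3203 probes at an unadjusted p under 0.05.

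**Figure D1:**
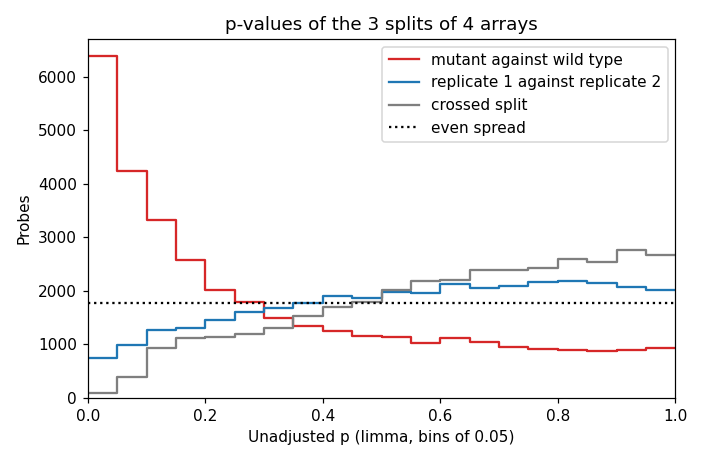
Number of probes per bin of unadjusted limma p for each of the 3 ways to split the 4 arrays into pairs, with an even spread dotted. The lowest bin held 6394 probes for eag mutant against eag wild type, 739 for replicate 1 against replicate 2 and 89 for the crossed split. In the last 2 splits a difference between genotypes adds to the spread within groups and lowers the count.

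The 2 differences that share no array, mutant replicate 1 minus wild type replicate 1 and mutant replicate 2 minus wild type replicate 2, correlated across probes with Pearson's r = 0.431 and Spearman's rho = 0.55. Probes are not independent replicates, and this r has no p-value. In 70.6% of probes both differences had the same sign. Both were at least 2-fold in the same direction for 1405 probes higher in the mutant and 314 lower, and of opposite sign for 45. With the wild type arrays exchanged, r was 0.298, the same sign was found in 66.5%, and 1283 probes were at least 2-fold higher and 337 lower in both differences, against 320 of opposite sign. The 2 differences within genotypes, which hold no genotype effect, correlated with r = 0.137. Simulated arrays without any effect gave -0.00984, but their noise was independent between arrays, so this value was built in and is no baseline for real arrays. Without the filter on background, which admits dim probes, the first r was 0.1869.

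**Figure D2:**
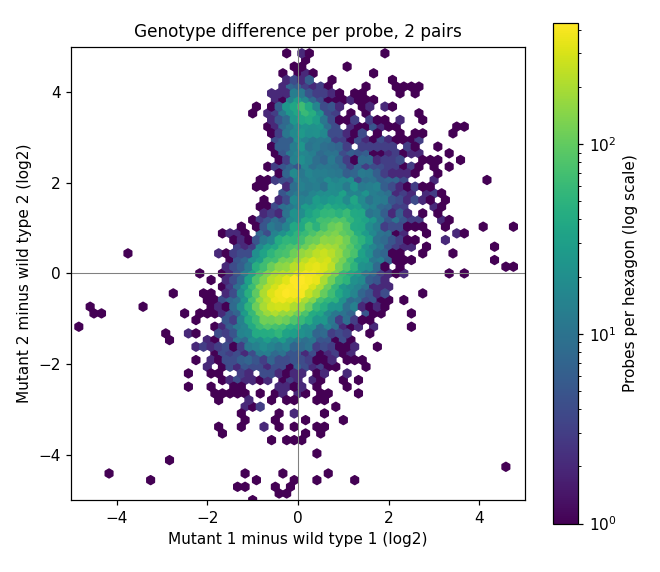
Each hexagon counts probes by the log2 difference between mutant and wild type in replicate 1 (horizontal) and in replicate 2 (vertical), with 35324 probes inside the plotted range and 42 outside. The main cloud is tilted along the diagonal (r = 0.431 over all probes), and a separate cloud near 0 on the horizontal axis and above 2 on the vertical one holds probes that were low on the array of wild type replicate 2 alone.

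The 2 probes with the smallest p in each direction illustrate the sizes, although none of the 4 passed the threshold. Probe fr00263 was 3.25 ± 0.32 log2 units higher in the mutant (SE, n = 2 per group, limma, Benjamini-Hochberg adjusted p = 0.222), with normalized log2 means of -1.25 and -4.50, and was well above background on 1 of the wild type arrays. The probe with the next ID number stood 3.06 log2 units higher. Probe fe03779 was not well above background on either wild type array, which makes its level at least 8.98-fold higher in the mutant against the detection limits of those 2 arrays (limma, Benjamini-Hochberg adjusted p = 0.222). In the other direction, probe fe05274 was not well above background on either mutant array and was at least 5.31-fold lower there, by the limits of those arrays. Its neighbour by number differed by -2.28 log2 units. Probe fe08196, measured on all 4 arrays, had a log2 difference of -2.22 ± 0.30 (SE, limma, Benjamini-Hochberg adjusted p = 0.222), and its neighbours by number had -1.46 and 0.66. These probes were picked among those whose 2 groups did not overlap. Leaving out an array, or changing the variance model, the block or the filter, could thus not turn the sign of their differences. Only the changes of normalization, background correction and floor tested it. Each of the 4 differences kept its sign in every alternative setting that gave it a value, while their fitted sizes moved. They ran from 2.03 to 3.39 log2 units for fr00263, from 1.77 to 4.87 for fe03779, from -2.77 to -0.87 for fe05274 and from -2.40 to -1.22 for fe08196, the smallest under normexp, or for fe03779 under a floor of 34.7 intensity units. The bounds given for fe03779 and fe05274 hold for the main processing with all 4 arrays, and some of these fitted sizes lie below them. Without eag wild type replicate 1, the adjusted p of these probes in limma lay between 0.00136 and 0.0198, within a range from 0.00136 to 0.526 over all alternatives.

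Probe IDs fell into 6 series by their leading letters, whose meaning is not given in the sources used here, and these groups were formed after the data were seen. In series fr, with 441 tested probes, the median difference lay 0.60 log2 units above that of all tested probes, and 90.5% of probes were higher in the mutant. At an unadjusted p under 0.05, 112 of its probes were higher and 2 lower, and 5 had an adjusted p under 0.05 when adjusted over the series alone (limma, Benjamini-Hochberg). The median of the series was above 0 in all 4 differences between a mutant and a wild type array, from 0.29 to 0.90. Series fv, with 494 tested probes, lay 0.36 log2 units above all tested probes, with 97 probes higher and 20 lower at an unadjusted p under 0.05, and 6 with an adjusted p under 0.05 over the series alone. The other 4 series lay between -0.08 and 0.10 of the median of all tested probes. With limma's camera at a preset correlation of 0.01, the shifts of fr (adjusted p = 1.24e-12) and fv (adjusted p = 0.000202) passed the threshold over the 6 series. With an estimated correlation neither did (adjusted p = 0.518 for both), and fry, which tests a series against no change and not against the other probes, gave an adjusted p = 0.142 for both. The shift of fr stayed above that of all tested probes in every alternative that gave log2 values, from 0.41 to 0.73, and that of fv from 0.18 to 0.44.

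**Figure D3:**
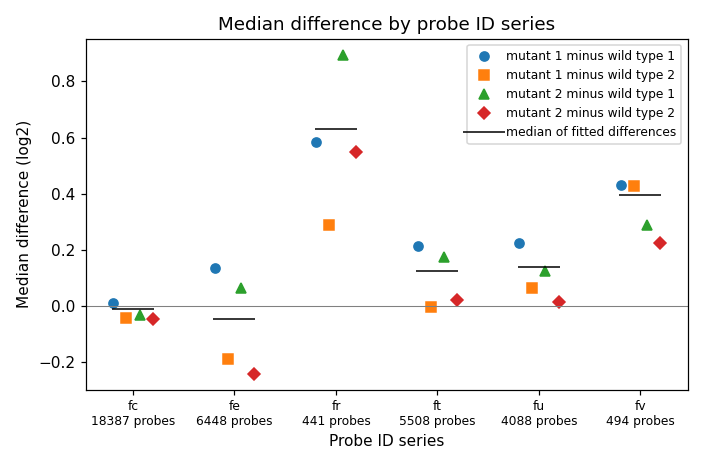
Median log2 difference of the tested probes of each ID series, as points for the 4 differences between a mutant and a wild type array and as a bar for the median of the fitted differences. Series fr lies between 0.29 and 0.90 in the 4 differences and series fv between 0.22 and 0.43, while the points of fc, fe and ft lie on both sides of 0.

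The log2 difference of the 2 wild type arrays had an SD of 0.832 over the tested probes, against 0.578 for the mutant pair and 0.678 to 1.022 for pairs of different genotype. By the median absolute deviation, which a minority of far probes hardly moves, the 2 pairs were close, with 0.473 and 0.438, and both lay below the 0.620 to 0.788 of pairs of different genotype. The array of eag wild type replicate 2 held 1291 probes (3.65%) at least 4-fold below each of the other 3 arrays, where the arrays of mutant replicates 1 and 2 and wild type replicate 1 held 10, 59 and 9. Their median difference from the mean of the other arrays was -3.22 log2 units, and 78.3% were still well above background. Of them, 87 had an unadjusted p under 0.05 in the comparison of genotypes (limma). Their choice by a gap between the wild type arrays makes their variance large and a small p rare. This count thus does not show how much they affect the comparison.

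**Figure D4:**
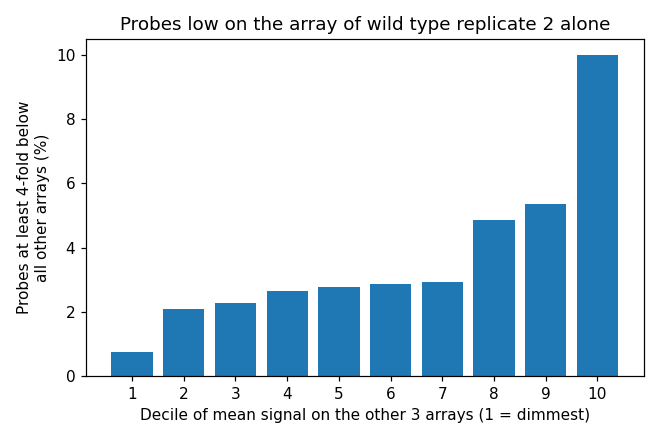
Percent of tested probes at least 4-fold below each other array on the array of eag wild type replicate 2, by decile of mean signal on the other 3 arrays. The share rises from 0.735% in the dimmest decile to 10% in the brightest.

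Probes well above background on both arrays of one genotype and on neither of the other were fewer for the mutant, with 93, than for the wild type, with 850. The mutant arrays were also the dimmer ones. After scaling, 93 of the 93 had a higher mean in the mutant, while 726 of the 850 had a lower one, with a median difference of -0.58 log2 units. These directions are no separate support, since the probes were picked by their signal on the same arrays. Scaling also raises the dimmer mutant arrays relative to the wild type arrays, which favours the direction of the 93. Splitting the arrays by replicate number in place of genotype gave 1360 and 56 such probes. With 1 array left out in turn, the counts lay between 138 and 864 for the mutant and between 1003 and 2794 for the wild type.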

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

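Tests chosen only after the result was seen were those of tiles, brightness, neighbours, splits of the arrays, runs of numbers, shifts between arrays and differences that share no array, and cyclic loess. The fits with an array left out and with quantile normalization were planned. Groups of 2 arrays are too small for a test of single outlying samples.

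Control probes, which take no part in the comparison of genotypes, also carried a signal. Of 10 E1A and 12 ERCC control probes, 2 had every spot well above background on at least 3 arrays. What RNA these 2 probes bound was not tested, so their levels are not known to be independent of the sample. The E1A probe had median intensities of 5479 and 3247 on the arrays of mutant replicates 1 and 2, and 11370 and 509.9 on those of wild type replicates 1 and 2. Relative to each array's 75th percentile, its level on the array of wild type replicate 2 was 13.6-fold below the mean of the others. The ERCC probe had 62.16 and 42.26 in the mutant, and 133.9 and 7.931 in the wild type. None of its spots was well above background on the array of wild type replicate 2, where its relative level was at least 4.49-fold lower. The bright corner control, the other control with every spot well above background on all 4 arrays, was not low there. Its median intensities were 1815 and 1898 in the mutant, and 2334 and 2996 in the wild type, or 2.12, 2.77, 1.37 and 2.43 log2 units relative to the 75th percentile.

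The same array of eag wild type replicate 2 held 1291 tested probes at least 4-fold below each other array. A local defect of the array would gather them in one place, but the highest share among 48 tiles of the array was 1.40 times the overall share, within the 1.29 to 1.67 that shuffling the probes gave. Noise of dim probes would put them among the dimmest, but their share was 13.6 times higher in the brightest decile than in the dimmest. Loss of single probes independent of their neighbours would leave neighbours by ID number at the share of other probes, but in series fc and fe 34.1% of 1070 neighbours were at least 2-fold low, 3.18 times the 10.7% given by shuffling within series and signal decile (8.97% to 12.5%). The amplification, the labelling and the cells of this sample stay open as sources, and no biological explanation was tested. The other array of its genotype did not share the pattern, which does not exclude a biological difference of this sample.

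The excess of probes at an unadjusted p under 0.05 between genotypes (6394, limma) was the highest of the 3 splits of the 4 arrays. Counting itself, 1 of 3 gave as many, and the highest other gave 739. With 3 splits, a share under 0.05 cannot be reached. Each other split mixes the genotypes on both sides, so a difference between genotypes adds to its spread within groups and lowers its count. The other splits are thus no baseline without effect. Scaling that depends on intensity may bend differences between dim mutant and bright wild type arrays, but after quantile normalization or cyclic loess at least 19.2% of probes, not necessarily the same ones, had an unadjusted p under 0.05. One deviating array would enter only one of 2 differences between genotypes that share no array, but these correlated with r of at least 0.298 in both pairings, against 0.137 for the differences within genotypes, although without mutant replicate 1 or 2 the count was 3254 or 3203. The eag genotype stays open as the source, untested, along with any other difference between the fly lines, the sorts, or the amplification and labelling of the samples. Both mutant arrays were dimmer than both wild type arrays before scaling. Normalization along intensity does not remove effects that differ between probes of like intensity, so these cannot be told apart from genotype.

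Series fr lay higher in the mutant, and dependence on intensity could shift a series of unlike brightness, but its median lay at percentile 100 of 10000 random sets of probes matched on mean signal, the highest of which had 0.22. Nor did a few runs of neighbouring probes carry it, since 100% of 49 runs of 10 consecutive numbers had a median above that of all tested probes. A shift of these probes between arrays whatever the genotype cannot be told apart from one of genotype, because the larger shift between 2 arrays of a genotype was 0.595 times that between genotypes. Relative to all tested probes, replicate 1 minus replicate 2 was -0.35 in the mutant and -0.20 in the wild type, and mutant minus wild type was 0.51 and 0.66 in the 2 rows of the slide, which are too few to settle it. What the series stands for is not given in the sources used here, and a response to the eag genotype was not tested separately.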

How the results depend on the processing

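The raised floor, cyclic loess, the restriction to the authors' probes and leaving out the probes low on wild type replicate 2 alone were chosen after seeing the data. Changed thresholds (adjusted p under 0.01, under 0.1, or under 0.05 with at least 2-fold) count among the alternatives but were applied to the main fit. Its smallest adjusted p was 0.222 (limma), so these thresholds could only give 0 and do not test the count. The count of probes at an adjusted p under 0.05 was 0 in 17 of 21 alternatives, and lay between 0 and 2729 when 1 array was left out, with 2729 without eag wild type replicate 1 and 1 without eag wild type replicate 2. With the low probes left out it was 274, and 380 when eag wild type replicate 1 was left out too. The count at an unadjusted p under 0.05 was within 1.5 times of 6394 in 14 of 18 alternatives. It was 3983 in the authors' table and 2941 for its probes with the scanner intensities, both over fewer probes, and between 3203 and 8861 when 1 array was left out. The share of these probes that were higher in the mutant turned below 50% with quantile normalization (37.74%), in the authors' table (45.42%) and for its probes (48.59%), and the cause was not tested. Quantile normalization moved the median of all tested probes from 0.03 to -0.10 and normexp moved it to 0.18. The correlation of the 2 independent differences was 0.1869 without the filter on background, which adds dim probes, and from 0.3895 to 0.5308 in the other 7 alternatives that can change it. Median centring, both variance models and the block leave it as it is by construction.

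With the replicate number as a block (replicate block, also the row of the slide), limma called 0 probes, with 7168 at an unadjusted p under 0.05, and no call changed. Deviations of arrays with one number correlated with r = 0.137 over 2 pairs, too few to count the numbers as a pairing.

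Not run, for want of gene names, were the alternatives for eag, gene lists, chromosomes and the mean of a gene's probes. Counting probes was already the unit, and leaving out saturated spots removed none. Named probes and the correlation have no value where a setting drops them or leaves 3 arrays. Signal over background limits folds of dim probes to bounds.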

Other observations

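Probes with consecutive ID numbers carried related signals in some series, an observation made after the data were seen. The genotype difference of a probe and that of the next number correlated across probes with r = 0.437 in series fc, 0.482 in fe, 0.677 in fv and 0.522 in fr, against 0.085 in ft and 0.186 in fu. At a distance of 2 numbers the correlation was -0.00292 in fc and 0.06 in fe, but 0.369 in fr and 0.359 in fv. At a distance of 5 it was 0.402 in fr and 0.067 in fv.

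The drop of probes on the array of eag wild type replicate 2 formed a separate group by size. In steps of 0.25 log2 units, 235 tested probes lay between -3.25 and -3 relative to the mean of the other arrays, against 152 in the step that begins at -2.5, and more again towards 0. The E1A control probe had a drop of -3.77 on this scale. Among the low probes, the 2 mutant arrays lay a median of 0.14 log2 units above wild type replicate 1. Low probes made up 9.11% of series fv, 4.47% of fc and 1.59% of fr.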
